A study of Drosophila melanogaster with 4 samples.

How the data were processed

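Chromatin from nuclei of adult fly heads (Drosophila melanogaster, the wild-type Oregon-R strain) was immunoprecipitated with an antibody against JHDM1 and sequenced. Per the labels, there were 2 ChIP libraries and 2 input libraries, and each input served as the background of the ChIP library with the same replicate number. Per the labels' protocols, heads were collected from whole adults with sieves, and homogenised tissue was fixed with formaldehyde. Nuclei were then lysed with SDS and sonication before immunoprecipitation on beads. Nothing in the labels says whether the replicates came from separate fly populations, so the spread between them may be technical.

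The submitters' processing notes name Bowtie 0.12.7, a short-read aligner. The values used here are 3 deposited lists of regions of significant enrichment, called clusters below: 1 for each ChIP replicate and 1 for the whole series, whose name marks it as that of the replicate set. Per the file headers, coordinates are those of FlyBase release 5. Each cluster carries a start, an end and a positive score assigned by the authors, and the unit of that deposited score is not given in the sources used here. The enrichment caller, its thresholds and the way the whole-series list was built are likewise not given in the sources used here. The score was therefore used to rank or filter clusters within a list, and agreement between lists was measured on ranks. In both replicate lists the shortest cluster was 1301 bp. In the whole-series list the shortest was 1001 bp and 100% of starts were even numbers, against 49.4% and 49.7% in the replicate lists. That list was therefore not treated as a simple merge of the other two.

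The read depth of the libraries is unknown here, and the precision of a score or a boundary could not be derived. A shallower library or a weaker immunoprecipitation yields fewer and shorter clusters, so covered length is given beside each count. The input libraries were not analysed here on their own. Shares of clusters are given with 95% Wilson binomial intervals, which cover counting error only and treat neighbouring clusters as independent.

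Clusters within a list did not overlap (0 overlapping neighbours in each of the 3 lists). In replicate 2 and in the whole-series list, 1 cluster each ran past the end of its arm and was trimmed to the arm length in the file header. Covered shares are the base pairs inside clusters divided by the length of the arm. The arms 2L, 2R, 3L and 3R are called the large autosomal arms. The 6 Het scaffolds, which hold mapped heterochromatin, and U, which holds sequence with no assigned chromosome, are called scaffolds. Clusters of different lists were called shared if they had at least 1 bp in common. The base-pair Jaccard index is the shared base pairs divided by the base pairs in either list. It was compared with 1000 circular shifts of replicate 2 along each arm in a two-sided test. Where no shift reached the observed value, p was set to 0.001, the smallest possible here, which counts a single tail. Scores were compared by Spearman's rho over clusters that were each other's best match, and covered shares over 100 kb bins. These correlations run across clusters or bins of the same libraries, which are not independent replicates, so they carry no p-value. With 2 ChIP libraries, sign flips of 2 values allow no two-sided p below 0.5, so no sign-flip test across replicates could pass a threshold of 0.05. Tests that assume a distribution of the values were not used here, and means are given with the SD.

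The overlap code was tested on simulated data before use. With known subsets of the 7836 clusters of replicate 1 copied into a second list, the planted shares and Jaccard indices were recovered with a difference of 0. Of 40 pairs of independent random lists with the lengths of the real clusters, 2 had p below 0.05 in 100 shifts each. The simulated clusters were placed uniformly at random along each arm. Real clusters vary in density along the arms, and the simulation did not cover that case. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

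The measures of overlap, sharing, score agreement and coverage per bin and arm, a first set of alternatives and the rule for named clusters were fixed before the data were examined. Further alternatives, and the comparisons of windows, arm ends, long clusters and 1 Mb bins, were added after the values were seen. The rule takes the 12 clusters with the highest score in the whole-series list that were shared with both replicates, given by coordinates. The first alternatives were other minimum overlaps, clusters at or above the median score or length of their list, other bin sizes, the 6 major arms alone and each replicate alone. Tests of gene 5′ ends, genomic features and fixed gene lists had been planned for an annotation of release 5. They were not run, because the gene table used here is that of Release 6, and coordinates of different releases were not mixed. That table served only to name the gene of the antibody's target, so clusters are described by position.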

Results

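The binding of JHDM1 along the genome was profiled in nuclei of adult Drosophila heads by ChIP-seq, in which DNA crosslinked to a protein is precipitated with an antibody and sequenced. JHDM1 belongs to the JmjC family of histone demethylases, and in the fly it is a synonym of the gene Kdm2 (CG11033). The question addressed was where in the genome this protein is enriched over input chromatin in head nuclei. The data comprised 2 ChIP libraries, each with its own input library, in 1 strain and 1 tissue, so the comparisons are between regions of the genome and between the replicates. Replicate 1 gave 7836 enriched clusters covering 27.4 Mb, or 19.6% of the arms and scaffolds. Replicate 2 gave 7074 clusters covering 25.1 Mb, or 17.9%. Clusters were kilobase-sized in both, with a median length of 2606 bp in replicate 1 and 2525 bp in replicate 2. Long clusters of more than 10 kb made up 2.88% of the list in replicate 1 and 3.87% in replicate 2. In each list longer clusters tended to have higher scores, with a Spearman's rho across clusters of 0.53 and 0.70.

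The first comparison asked whether both immunoprecipitations marked the same places. Of the clusters of replicate 1, 77.4% (95% interval 76.5 to 78.3%) touched a cluster of replicate 2, and 86.1% (85.3 to 86.9%) of the clusters of replicate 2 touched one of replicate 1. Randomly shifted clusters gave mean shares of 32.8% and 36.1%. In base pairs, 19.5 Mb lay in clusters of both replicates, a Jaccard index of 0.592. The index averaged 0.12 over 1000 circular shifts and reached at most 0.189. The overlap thus exceeded random placement (permutation p = 0.001, the smallest that this test can give). On the large autosomal arms 83.2% of the clusters of replicate 1 and 85.4% of those of replicate 2 were shared. The shares were lower on the scaffolds, at 30.4% (25.9 to 35.3%) and 65.5% (57.9 to 72.3%). No share from shifts was computed for the scaffolds alone. They were covered more thinly than the arms, so the genome-wide 32.8% and 36.1% are not their random expectation. On the X, 93.0% of the clusters of replicate 2 were shared but only 65.5% of those of replicate 1, so the X clusters of replicate 2 were largely a subset of those of replicate 1. Clusters with higher scores were more often shared. They were also longer, and longer clusters touch others more often by chance, so score and length were not separated here. In the highest quartile by score, 88.1% of clusters in replicate 1 and 99.0% in replicate 2 were shared, against 69.3% and 76.7% in the lowest quartile. The rank of the score was only moderately reproducible, with a Spearman's rho of 0.51 across 5238 matched pairs of clusters. The share of 100 kb bins that was covered agreed more closely between the replicates, with a rho of 0.94 across 1405 bins.

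The second comparison was between chromosomes. Chromosome 4, the small autosome of the fly, which is rich in repeats and in heterochromatin proteins, was the most densely covered arm or scaffold. Clusters took up 50.9% ± 0.72 of it (mean ± SD, n = 2 replicates), against 21.7% ± 0.13 of the large autosomal arms together. This was a 2.34 ± 0.019 fold difference (SD, n = 2), many times the spread between the replicates. Among the large autosomal arms, 2R was the most covered at 24.5% ± 0.089, against 20.3% ± 0.33 on 2L, 20.7% ± 0.71 on 3L and 21.8% ± 0.16 on 3R. No window of the length of chromosome 4 on those arms or on the X was as densely covered as that chromosome. There were 2248 overlapping windows, placed every 50 kb along the 5 large arms. Their highest covered share was 36.5% in replicate 1, on the X, and 36.8% in replicate 2, on 3R. The scaffolds lay at the other extreme. Of their length 3.39% ± 1.40 (SD, n = 2) was covered, with 3.44% ± 1.46 on the Het scaffolds together and 3.34% ± 1.34 on U. Among the Het scaffolds, XHet had the highest share at 11.1% ± 0.79, with 6 clusters in replicate 1 and 4 in replicate 2. YHet had the lowest at 1.52% ± 1.43, with 2.54% from 5 clusters in replicate 1 and 0.51% from 1 in replicate 2. In the whole-series list YHet had 10 clusters and a share of 3.84%, above the 3.80% of 3LHet. How much of the scaffold sequence could be mapped uniquely is not known here, and a lower mappable share would lower these values.

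**Figure D1:**
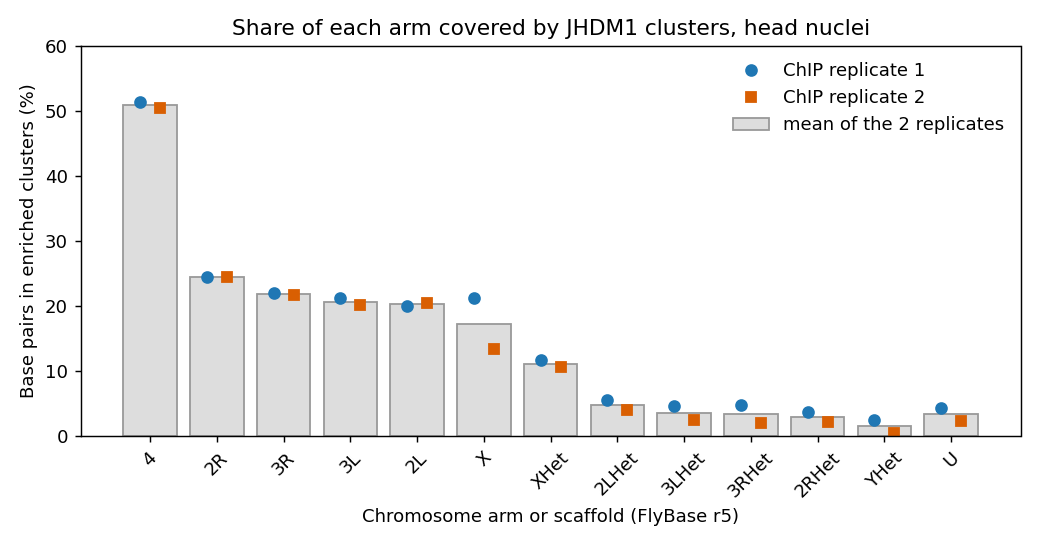
Share of the base pairs of each chromosome arm or scaffold (x axis, FlyBase r5 names) that lay in enriched clusters (y axis, percent); bars are means of the 2 ChIP replicates and points are the single replicates. Chromosome 4 stands at 51.5% and 50.4%, the X at 21.2% in replicate 1 and 13.4% in replicate 2, and the Het scaffolds and U below 12%.

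The X chromosome was the large arm on which the replicates differed. Its covered share was 21.2% in replicate 1, close to the 21.8% of the large autosomal arms, and 13.4% in replicate 2, where the large autosomal arms stood at 21.7%. The ratio of replicate 2 to replicate 1 was 0.635 on the X, against 1.02 on 2L, 1.01 on 2R, 0.953 on 3L, 0.990 on 3R and 0.980 on chromosome 4. The number of X clusters was 1407 in replicate 1 and 1064 in replicate 2, a ratio of 0.756. Chromosome 4 had a similar fall in number, from 143 to 113 (ratio 0.790), while its covered share hardly changed. The difference in coverage ran along the whole X. All 22 of its full 1 Mb bins were less covered in replicate 2, as were 54 of 95 bins of the large autosomal arms. The ratio per bin ranged from 0.434 to 0.833 on the X and from 0.757 to 1.42 on the large autosomal arms. Scaffolds were also less covered in replicate 2, with 362 clusters in replicate 1 and 165 in replicate 2 and a ratio of covered shares of 0.548. On U there were 167 and 75 clusters. These are differences between 2 libraries with no replicate of their own, and no test was made of them. The X can therefore be compared with the autosomes only within each library, at 0.970 fold in replicate 1 and 0.621 fold in replicate 2.

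Along the arms, coverage was uneven on the scale of megabases, and dense and sparse regions coincided in the replicates. By the mean of the replicates, the densest full 1 Mb bins lay on 3R from 5 to 6 Mb (35.0% ± 0.077, SD, n = 2), on 2L from 10 to 11 Mb (34.4% ± 0.18) and on 2R from 5 to 6 Mb (34.2% ± 2.11). The X from 15 to 16 Mb was covered at 34.7% in replicate 1, more than the 34.3% of that 2L bin, and at 28.2% in replicate 2. The sparsest were on 3L from 23 to 24 Mb (5.70% ± 1.11) and on 2L from 14 to 15 Mb (7.68% ± 0.060). The 1 Mb at the centromeric end of the assembled arm was thinly covered on 3L (4.04% ± 0.83, SD, n = 2), X (8.56% ± 2.48), 2L (10.8% ± 0.92) and 2R (12.3% ± 0.44). The 1 Mb at the telomeric end of the same arms was covered at 27.3% ± 0.028, 17.7% ± 2.28, 24.7% ± 2.81 and 23.9% ± 0.64 respectively. On these 4 arms the difference between the ends exceeded the SD between replicates. Arm 3R went the other way, with 26.0% ± 0.020 at the centromeric end of the assembled arm and 18.8% ± 0.75 at the telomeric end. As for the scaffolds, the share of these ends that could be mapped uniquely is not known here.

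**Figure D2:**
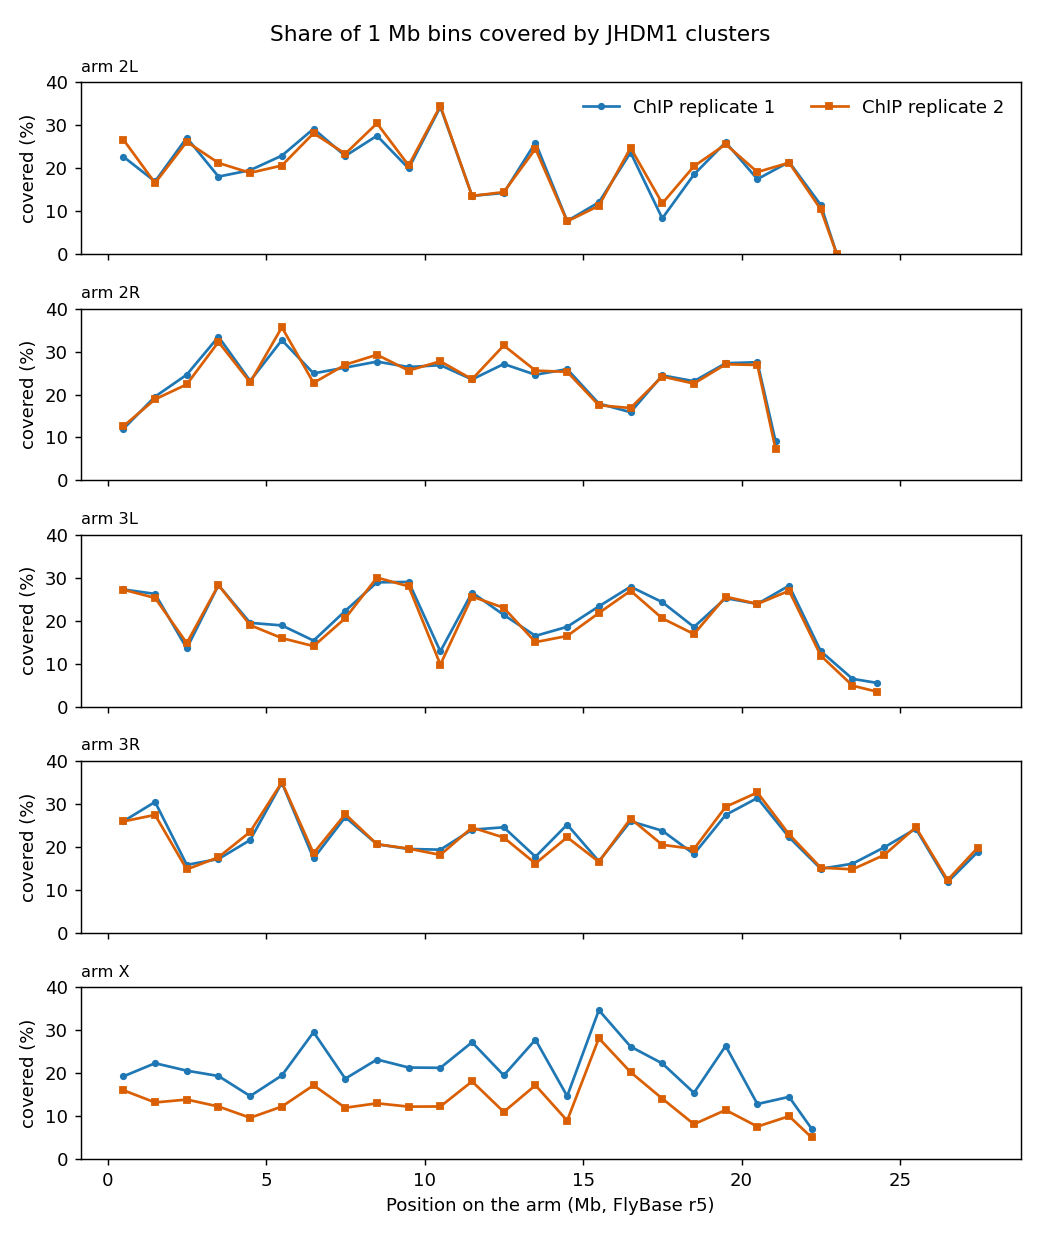
Share of each 1 Mb bin covered by clusters (y axis, percent) against position on the 5 large arms (x axis, Mb, FlyBase r5), with 1 line per ChIP replicate. The lines cross on 2L, 2R, 3L and 3R, with gaps in single bins such as 2L from 17 to 18 Mb (8.35% and 11.8%), whereas on the X replicate 2 runs below replicate 1 in every full bin.

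Clusters on chromosome 4 were more closely spaced than on the large autosomal arms, with 106 per Mb against 61.3 in replicate 1 and 83.6 against 59.3 in replicate 2, and more of them were long. Clusters over 10 kb held 40.1% of its covered base pairs in replicate 1 and 62.2% in replicate 2, against 11.0% and 15.5% on the large autosomal arms. Chromosome 4 held 143 of the 7836 clusters of replicate 1 and 113 of the 7074 of replicate 2. Of the 100 longest clusters, 14 in replicate 1 and 13 in replicate 2 lay on it. Of the 100 with the highest scores, 0 did in either list. With so few clusters on the chromosome, that 0 alone does not show a lack of high scores. Of the 500 with the highest scores, 3 in replicate 1 and 0 in replicate 2 lay on it. That is a smaller part than its part of the lists. The mean score percentile on chromosome 4 was 49.2 in replicate 1 and 45.6 in replicate 2, against 47.2 and 49.8 on the large autosomal arms. Among the 12 longest clusters of the whole-series list that both replicates shared, 5 were on this chromosome, named here after their lengths were seen. The longest ran over 52.5 kb from 456260 to 508756, where replicate 1 had 4 separate clusters and replicate 2 had 3. The others spanned 879540 to 919062, 1130232 to 1168790, 576616 to 611170 and 1046294 to 1075640. Coverage was not uniform along the chromosome: the 100 kb bins from 200001 to 400000 were covered at 66.3% and 66.9% on average, the bin from 700001 to 800000 at 22.8%, and the last, partial bin at 15.2%. Without clusters over 10 kb, chromosome 4 was covered 1.59 fold as much as the large autosomal arms in replicate 1 and 1.04 fold in replicate 2, counted over the full length of each arm. Outside chromosome 4, the longest shared clusters were on 2L from 10237918 to 10280246 (42.3 kb) and on 3L from 222150 to 262244 (40.1 kb).

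**Figure D3:**
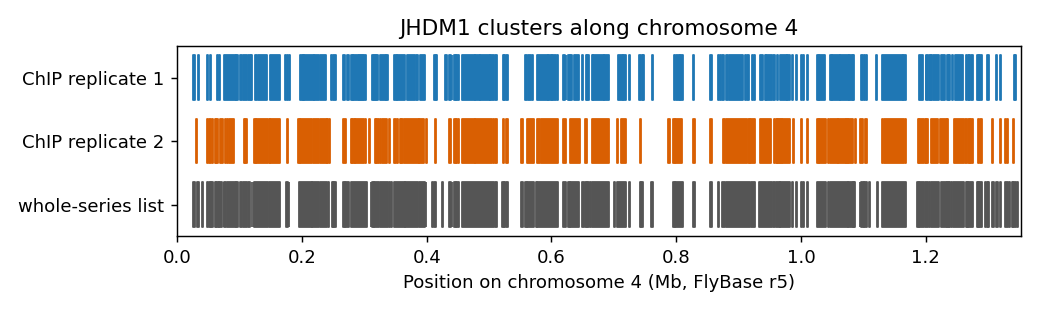
Clusters along chromosome 4 (x axis, Mb, FlyBase r5) in ChIP replicate 1, ChIP replicate 2 and the whole-series list, 1 row each, drawn to scale. Broad blocks recur at the same places in both replicates, and the bin from 700001 to 800000 is sparse in both (26.6% and 18.9%). The whole-series list is that of the same replicate set and is not a separate observation.

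The highest scores were found on unplaced sequence. Of the 12 clusters with the highest scores in the whole-series list that both replicates shared, 11 lay on U and 1 on 3RHet, from 2348000 to 2350906. Clusters on U made up 2.13% of the list in replicate 1 and 1.06% in replicate 2, and in each replicate 11 of the 12 highest scores were on U. The top 2 clusters were close neighbours, from 2661978 to 2667712 and from 2671686 to 2679832. The authors' scores for the first were 6.42, rank 1, in replicate 1 and 4.65, rank 5, in replicate 2. A group of 3 clusters lay between 2154612 and 2172638, and the longest of the 12 ran over 28.8 kb from 1987150 to 2015978. The others on U spanned 3467636 to 3488014, 7712540 to 7716508, 7774166 to 7777966, 7843018 to 7846522 and 9500998 to 9504386. All 12 ranked among the 28 highest scores in replicate 1 and the 15 highest in replicate 2. They were chosen by score in the list of the replicate set of these same libraries. High ranks in each replicate therefore follow in part from that choice. On the 6 major arms, the highest-scoring shared clusters, chosen after their scores were seen, were on X from 5417272 to 5420004 (score 3.72 in the whole-series list), on 2R from 15612012 to 15617826 (3.63) and on 3R from 13440132 to 13447192 (3.48). They ranked 29, 26 and 55 by score in replicate 1 and 17, 21 and 14 in replicate 2, with the same limit on these ranks. The chromosomal origin and copy number of the U sequences are not known here.

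The whole-series list held 8005 clusters covering 31.4 Mb. Of these, 64.8% (95% interval 63.7 to 65.8%) touched clusters of both replicates, 17.1% of replicate 1 only, 7.56% of replicate 2 only and 10.5% of neither. Clusters found in both replicates were longer, with a median of 3775 bp, than those found in neither, with a median of 1197 bp. No cluster of the replicate lists was shorter than 1301 bp, and longer clusters touch others more often by chance. The difference in length may follow in part from these limits, and so may the shares found in neither. Chromosome 4 was covered at 61.0% in this list and the large autosomal arms at 25.6%, a 2.38 fold difference. The X was covered at 22.2%, and 29.1% of its clusters in this list touched clusters of replicate 1 only. That share was 13.4% on the large autosomal arms, 24.8% on chromosome 4 and 30.3% on the scaffolds. The scaffolds had the largest part without a counterpart, with 33.1% (28.4 to 38.3%) of their clusters in neither replicate. Conversely, 93.2% of the clusters of replicate 1 and 93.4% of those of replicate 2 touched the whole-series list.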

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

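Of 32 alternative settings computed, 22 moved a value beyond the spread set for its measure. The other 10 stayed within it or, for the Jaccard index, still exceeded the shifts. A change of direction was possible only for the Jaccard index, the fold of chromosome 4 and the ratio of the X, and did not occur. Only the Jaccard index carried a test, so no other result had a call that could end. The settings that leave out the X, restrict to scaffolds, or concern chromosome 4 and the ratio of the X were chosen after seeing the data. The Jaccard index exceeded its circular shifts under each alternative tried (permutation p = 0.001, the smallest possible). A minimum overlap of 50% of a cluster's own length lowered the shared shares to 70.2% in replicate 1 and 79.1% in replicate 2, and a reciprocal overlap of 50% to 52.2% and 57.8%. Restricted to clusters at or above the median score of their list, they were 63.1% and 71.9%, since a match below the median of the other list no longer counts. The whole-series clusters found in both replicates went from 64.8% to 59.4% at 50% of their length, and a single replicate gave 72.4 to 81.9%. The rank correlation of the scores was 0.564 at reciprocal 50%, 0.546 without the X and 0.762 on scaffolds alone. That of the bins was 0.928 at 50 kb, 0.931 at 500 kb and 0.932 on the 6 major arms. The fold of chromosome 4 was 2.38 in the whole-series list, 2.83 above the median score, 1.57 as clusters per Mb and 1.31 without clusters over 10 kb. The ratio of the X between replicates was 0.559 above the median score, 0.538 above the median length, 0.756 as clusters per Mb and 0.657 without clusters over 10 kb. The large autosomal arms stood at 1.17, 1.02, 0.968 and 0.942 under these settings, so the X was lower under each. No paired analysis was possible because the input libraries have no values of their own here. The tests of gene 5′ ends, features and gene lists were not run, and the unknown read depth leaves open how many weak clusters each library missed.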

Other observations

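All tests in this part were chosen after the result they bear on was seen. Clusters on U made up 2.13% of the list in replicate 1 and 1.06% in replicate 2. Of the 500 clusters with the highest scores, 66 in replicate 1 and 34 in replicate 2 lay on U, while chromosome 4 had 3 and 0. In the full lists chromosome 4 held 143 of 7836 clusters in replicate 1 and 113 of 7074 in replicate 2, a larger part than among those 500. Of the 500 longest, 27 and 29 lay on chromosome 4 and 4 and 4 on U. Scaffold clusters were fewer in replicate 2. Across the 107 matched pairs on scaffolds, rho of the scores was 0.76, against 0.54 across 4219 pairs on the large autosomal arms. It was 0.51 across 77 pairs on chromosome 4 and lowest on the X, at 0.34 across 835 pairs.

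The lower coverage of the X in replicate 2 was not an equal loss on every arm. The ratio of covered shares on the large autosomal arms was 0.992. That ratio is part of the pattern itself. Read depth is unknown, so a lower yield that acts unevenly between arms stays open. The lower coverage was also not the work of a few stretches of the X. Of its 22 full 1 Mb bins, 22 fell below the autosomal 5th percentile of 0.877. Among 835 matched pairs on the X, the median change of the score percentile was −10.6 points (95% bootstrap interval −12.6 to −8.07, over the sampling of clusters only), against 2.06 points on the large autosomal arms. Percentiles were taken over the matched pairs of all arms together, so a fall on the X by itself raises the other arms. The change on the X describes the same lower enrichment in another measure, with 1 library per side. It therefore does not decide the cause. A different share of male heads in the ChIP and its input could lower the X and should then raise the Y. YHet had 5 clusters in replicate 1 and 1 in replicate 2 (16.7% in replicate 2, exact 95% interval 0.421 to 64.1%), too few to decide. The scaffolds together also fell, from 362 clusters to 165. A fall on YHet would therefore not decide the question even with more clusters. The labels give no difference between the replicates, and no biological explanation beyond the share of males was tested.

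The high coverage of chromosome 4 exceeded that of stretches of this length on the large arms, where 0 of 2248 windows reached it in either replicate. The windows were placed every 50 kb and overlap, so they stand for far fewer separate stretches. Chromosome 4 was singled out because its coverage was the highest of any arm. This high coverage did not rest on a few single clusters. Those over 10 kb numbered 17 in replicate 1 and 24 in replicate 2. The longest held 32991 of 695564 covered bp in replicate 1 and 34012 of 681846 in replicate 2. How far the high coverage rests on the long clusters as a group stays open. Without clusters over 10 kb the fold was 1.59 in replicate 1 and 1.04 in replicate 2. That setting also removes ordinary enrichment wherever neighbouring clusters were joined, and keeps the removed stretches in the length of the arm, so it cannot separate broad binding from dense binding.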
